A study of Mus musculus with 16 samples.

How the data were processed

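RNA of 16 mouse samples described as tumours was sequenced, 3 wild-type and 3 Trp53bp1 knockout samples of the ID8 line and 5 of each genotype of the KPC line. Groups and replicate numbers come from the labels. The labels' protocols describe RNA taken from cells with a column kit, and the samples as tumours grown from implanted lines. Reads were processed with HISAT and RSEM 1.2.8 on GRCm39 (mm39), per the submitters' processing notes. The deposited values are expected counts per gene, of which 7.92% to 8.96% per table are not whole, and they were not normalized as far as the values show. Each of the 4 tables lists only genes with a value above 0 in at least 1 of its samples. A gene missing from a table was taken as 0, and expected counts were rounded to whole numbers. All 16 columns were matched to a sample.

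Totals per library ranged from 17902867 to 19727536 counts, so 3 counts correspond to 0.1521 to 0.1676 CPM. Intervals and floors cover counting error only. Replicates of each group differed by more than sampling noise (chi-square per gene of 4.36 or more), and none was counted as a duplicate.

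Tests used edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05. Each line was fitted alone, and the difference between lines was an interaction contrast over all 16 libraries. The standard error printed is the log2 fold change divided by the square root of F, which is an approximation. The targeted gene was also tested by an exact permutation test. Before the data were examined, 34 gene lists were fixed, and those with at least 3 tested members were tested with camera (correlation preset at 0.01, or estimated per list) and fry, adjusted over lists. Overlap between lines was set against n1 × n2 / N per direction, with Fisher's exact test. Genes named are Trp53bp1, the 6 largest increases and 6 largest decreases per line among called genes with a mean log2 CPM of at least 1 and no overlap of groups, 2 members per passing list and of 5 lists in every case, the 5 interaction genes of smallest p, and up to 6 genes called alike in both lines. Predicted genes, Rik genes, antigen receptor segments and pseudogenes were not named. Acta1 and the host markers Ptprc, Adgre1, Lyz2, Cdh5, Pecam1, Hbb-bs and Krt8 were named after their values had been seen.

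Alternatives were median-of-ratios size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no filter, a filter at 1 CPM, a log2 fold cut of 1, a replicate block, a joint fit of the 4 groups, genes listed in both tables, removal of haemoglobin and immunoglobulin genes, and leaving out each library. A muscle score covariate, removal of libraries with Acta1 above 1000 CPM and removal of 3 chromosomes were added after the data were seen. The procedure was tested on 10 simulations per comparison with 200 changed genes. For ID8 (11933 genes) it recovered 84.6%, 94.3% and 97.6% of genes changed 1.5, 2 and 4-fold, and 7.86% of its calls were false, above the nominal 5%. For KPC (14283 genes) it recovered 39.8%, 75.4% and 91.7%, with 5% of calls false. For the interaction (14921 genes) it recovered 16%, 50.8% and 70.1%, with 3.14% false. The 200 changed genes are fewer than the 6067, 1953 and 3259 called in the data, and genes were simulated as independent. These rates need not hold for the real calls.

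Lists of mitochondrially encoded genes and of Y chromosome genes with Xist had too few listed members and were not analysed here. Interferon ligands had 3 listed members, of which 0 passed the count filter in either line, and were not analysed here either. The reference annotation at hand is GRCm38.p6, another build than that of the tables, so no coordinates are given, and chromosome assignments come from that assembly (11876 of 11933 genes tested in ID8 matched). The counting tool can split reads among near-identical genes such as the Oas1 and Gbp families, so single members of these are uncertain.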

Results

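Mouse tumour lines with and without a knockout of Trp53bp1, the gene of the DNA repair factor 53BP1, were profiled by RNA sequencing. All samples are described in the labels as tumours that formed from lines implanted in syngeneic mice. ID8 is a mouse ovarian surface epithelial cancer line, and KPC is a mouse pancreatic cancer line. The 16 libraries formed 4 groups, with 3 wild-type and 3 knockout samples for ID8 and 5 wild-type and 5 knockout samples for KPC. Total counts per library were 19450799 to 19727536 in ID8 wild type, 18963859 to 19072437 in ID8 knockout, 17902867 to 19302932 in KPC wild type and 18452327 to 19170258 in KPC knockout. The biological coefficient of variation was 5.08% in ID8 and 25.1% in KPC, and the median standard error of a log2 fold change was 0.0681 in ID8 and 0.12 in KPC. Most members of the fixed host cell lists were under 0.1 of their mean KPC level in ID8, namely 18 of 21 T cell, 19 of 20 macrophage, 11 of 14 dendritic cell, 12 of 14 endothelial, 7 of 8 erythroid and 15 of 20 fibroblast genes. Exceptions included Esam of the endothelial list (140 CPM in ID8 and 47.6 in KPC), Flt1 (30.1 and 49.8), Ccr7 of the dendritic list (38.9 and 30.1), and Sparc (2740 and 3070) and Dcn (513 and 385) of the fibroblast list. Ptprc, the pan-leukocyte marker CD45, Cdh5 of endothelial cells and Hbb-bs of red blood cells had 0 counts in every ID8 library, while KPC libraries had Ptprc at 51.1 to 217 CPM, Cdh5 at 81.2 to 131 CPM and Hbb-bs at 29 to 81.4 CPM.

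**Figure D1:**
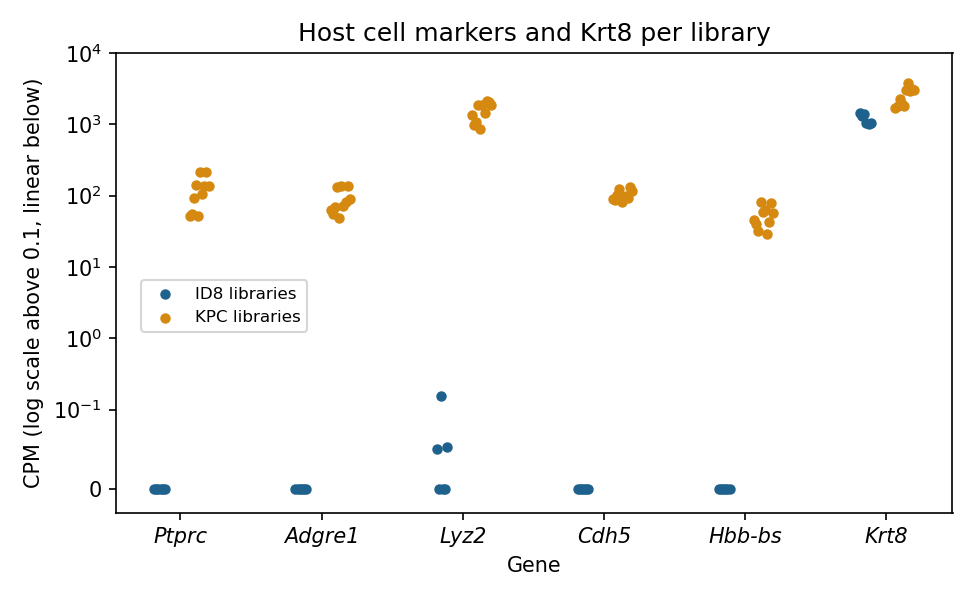
CPM of 5 host cell markers and of the epithelial keratin Krt8 in each of the 6 ID8 and 10 KPC libraries, on an axis that is logarithmic above 0.1 and linear below. Ptprc, Adgre1, Cdh5 and Hbb-bs are at 0 in all ID8 libraries, and Lyz2 reaches at most 0.154 CPM there.

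Trp53bp1 was lower in the knockout libraries of both lines. In ID8 it was 46.08 ± 2.89 CPM in wild type and 18.38 ± 0.502 CPM in knockout (SD, n = 3 each), which is 39.9% of wild type. The log2 fold change was -1.33 (SE 0.0667, edgeR adjusted p = 1.15e-10), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples can give. In KPC it was 51.5 ± 3.59 CPM in wild type and 34.14 ± 3.99 CPM in knockout (SD, n = 5 each), which is 66.3% of wild type. The log2 fold change was -0.59 (SE 0.0898, edgeR adjusted p = 0.004), with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 samples can give. The groups did not overlap in either line. The decrease was smaller in KPC by 0.76 on the log2 scale (SE 0.121, edgeR interaction adjusted p = 0.000525). Host cells of a tumour are not knocked out, and KPC libraries held host transcripts (Ptprc at 51.1 to 217 CPM, with 0 counts in ID8). The smaller decrease therefore cannot be read as a weaker knockout in KPC cancer cells. The share of Trp53bp1 transcript from host cells was not tested. Transcript that remains after a knockout does not measure the protein, and the deleted part of the gene is not given in the sources used here.

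**Figure D2:**
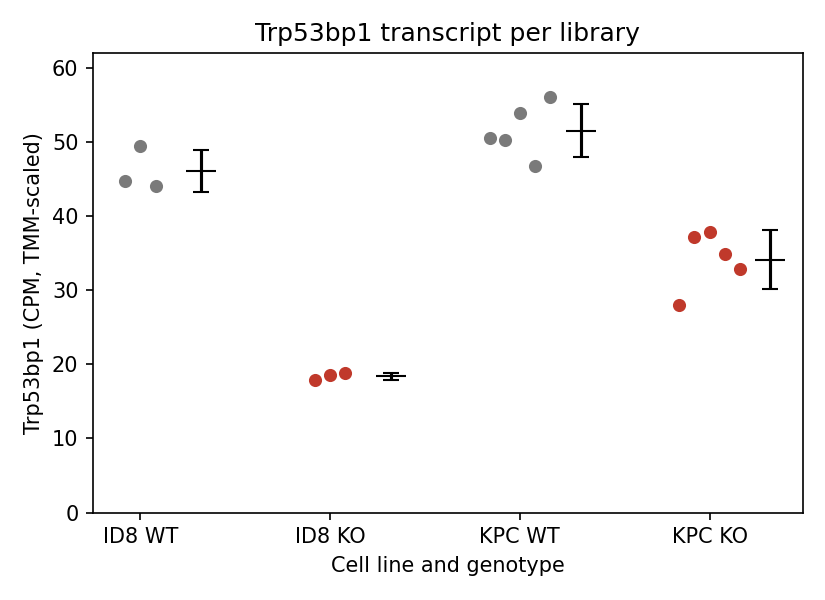
Trp53bp1 in CPM per library (points) with the group mean and SD (bar) for ID8 and KPC, wild type (grey) and knockout (red). Knockout libraries lie between 17.83 and 18.81 CPM in ID8 and between 27.94 and 37.89 CPM in KPC, below all wild-type libraries of their line.

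Knockout of Trp53bp1 in ID8 came with higher interferon-stimulated and inflammatory genes, which passed as lists with an estimated correlation too (adjusted p = 0.0393 and 0.00914). Here and below, list members counted as rising or falling, or as higher or lower, are those that passed an edgeR adjusted p of 0.05. Other members can have a change of the same sign. Among interferon-stimulated genes, 42 of 44 tested members rose and none fell, with a median log2 change of 1.26. Oas1a, an antiviral oligoadenylate synthetase, rose from 0.683 ± 0.192 to 14.5 ± 2.29 CPM (SD, n = 3 each), and Oasl2 rose from 23.67 ± 1.00 to 69.98 ± 7.49 CPM. Among inflammatory cytokines and NF-kB targets, 12 of 13 rose, with a median log2 change of 3.47. The chemokine gene Ccl2 rose from 19.28 ± 1.68 to 239.5 ± 10.1 CPM, and Vcam1, an adhesion molecule, rose from 15.93 ± 0.726 to 178.4 ± 8.75 CPM. In all, 6067 of 11933 tested genes passed an edgeR adjusted p of 0.05, 3027 higher and 3040 lower, of which 256 and 491 changed at least 2-fold. Each genotype is represented by a single line in the labels, for KPC as well. The p-values therefore cannot separate the knockout from a clonal difference between the lines compared. Groups did not overlap for 58% of genes, where chance gives 10%.

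Other fixed lists in ID8 moved in both directions. Of the interferon-gamma response, 15 of 17 members rose, among them the guanylate-binding protein genes Gbp2 (log2 change 2.23, SE 0.0604) and Gbp6 (2.45, SE 0.097). All 3 tested T cell recruiting chemokines rose, among them Cxcl10 from 1.86 ± 0.725 to 18.34 ± 0.722 CPM. Of the p53 targets 15 of 20 rose and 2 fell, with a median of 0.355. Pmaip1, the gene of the cell death factor Noxa, had 9.55 ± 0.373 CPM in wild type and 0 counts in all knockout libraries. Its level was at least 62.1-fold lower, against a floor of 3 counts per library (0.154 CPM on the TMM scale of these values). The sign of the list's mean rests on this gene, as the mean was 0.112 with Pmaip1 at that bound and -0.116 with its fitted value. With an estimated correlation the p53 list had an adjusted p of 0.135. The mesothelial list also passed upward, with 6 of 10 members higher and 2 lower and an adjusted p of 0.217 with an estimated correlation. Of hypoxia and glycolysis genes 18 of 20 fell and 1 rose, with a median of -0.902 and an adjusted p of 0.135 with an estimated correlation. The pyruvate dehydrogenase kinase gene Pdk1 fell from 358.9 ± 20.6 to 143.5 ± 3.56 CPM. Fibroblast and extracellular matrix genes (9 of 13 lower, 1 higher), epithelial genes (6 of 11 lower) and ovarian steroidogenic genes (3 of 3 lower) passed downward, with adjusted p of 0.292, 0.263 and 0.217 with an estimated correlation. The cGAS-STING list did not pass (median 0.149, camera adjusted p = 0.195), with 9 members higher and 3 lower of 17. Zbp1, a sensor of nucleic acids, rose by a log2 change of 2.95 (SE 0.219), and Enpp1, which degrades the messenger cGAMP, fell by 0.60 on the log2 scale (SE 0.054). The interferon-gamma and chemokine lists had an adjusted p of 0.00914 and 0.0393 with an estimated correlation. With it, 4 of the 10 list calls held. By fry, which does not set a list against other genes, 18 of 23 tested lists passed, these 10 among them. In these libraries 19 of 20 macrophage and 18 of 21 T cell list members were under 0.1 of their KPC level.

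The genes with the largest fitted increases in ID8 knockout were Saa3, an acute phase protein gene (log2 change 7.20, SE 0.189), Oas2, Oas1g, Steap4, the chemokine gene Ccl20 and Neurl3. Oas2 had 2 counts over all wild-type libraries and 320 over all knockout libraries, a ratio of 156 with a 95% counting interval of 42.9 to 1300. Defb29, Tspan11, A4galt, Slc44a3 and Myl9 were among the largest fitted decreases, and Pmaip1, with only a bound, has no rank among them. Defb29 fell from 19.57 ± 2.94 to 0.0854 ± 0.0294 CPM, and Myl9, a myosin light chain gene, fell from 5.32 ± 0.785 to 0.171 ± 0.119 CPM.

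Single genes of myeloid and cytotoxic cells were higher in KPC knockout than in KPC wild-type libraries, with a wide spread between samples. The immune cell lists did not pass with an estimated correlation (adjusted p = 0.39 each), while each passed by fry (adjusted p of 0.0234 to 0.0461). Chil3 and Chil4, chitinase-like genes of myeloid cells, rose from 3.13 ± 1.25 to 60.56 ± 24.97 CPM and from 2.13 ± 3.76 to 1188 ± 1127 CPM (SD, n = 5 each). Gzma, a cytotoxic granule protease gene, rose from 1.08 ± 1.02 to 6.98 ± 1.39 CPM, and Arg1, an arginase of myeloid cells, rose from 110.2 ± 40.0 to 338.5 ± 81.2 CPM. The epithelial tight junction genes Cldn7 and Cldn3 rose from 17.39 ± 2.96 to 58.52 ± 5.53 CPM and from 20.61 ± 4.31 to 58.32 ± 3.597 CPM, while Ocln, another tight junction gene of the same list, named after its values were seen, fell from 16.44 ± 4.75 to 8.10 ± 0.93 CPM. In all, 1953 of 14283 tested genes passed an edgeR adjusted p of 0.05, 952 higher and 1001 lower, of which 365 and 185 changed at least 2-fold. Groups did not overlap for 11.8% of genes, where chance gives 0.794%. With a skeletal muscle score as a covariate, an alternative chosen after the data were seen, 335 genes passed, and 34 of 60 named gene values lost their call, among them Gzma (log2 change 2.69, SE 0.584, and 2.64, SE 0.692, with the covariate), Zap70, Cd2, Cd274 and Sting1, with a median of 93% of the log2 change left and SEs a median of 1.27 times as large. Leaving out each library in turn gave 934 to 3106 genes, the latter without wild-type replicate 4.

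In KPC, 21 of 30 tested lists passed camera with a preset correlation, 17 upward and 4 downward, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.177. By fry 15 passed, and at an unadjusted edgeR p under 0.05 the genes numbered 4637. Of T cell genes, 2 of 21 rose (Zap70 and Cd2), with a median log2 change of 1.51. Of cytotoxic T and NK cell genes 6 of 18 rose (median 1.54), of regulatory T cell genes 5 of 8 (1.55), of B and plasma cell genes 5 of 7 (1.65), of dendritic cell genes 8 of 14, with 1 lower (1.48), of neutrophil genes 3 of 14 (0.517) and of macrophage genes 2 of 19 (0.687). For these lists the adjusted p was 0.39 with an estimated correlation and 0.0234 to 0.0461 by fry, which does not set a list against other genes. Adjusted over the list alone, 9 T cell, 12 cytotoxic and 14 macrophage genes were higher. By sign alone, changes were positive for 20 of 21 T cell, 18 of 18 cytotoxic, 8 of 8 regulatory T cell and 7 of 7 B and plasma cell genes. The same held for 13 of 14 dendritic cell, 13 of 14 neutrophil and 19 of 19 macrophage genes. Members of these lists moved together, with an estimated correlation of 0.336 (neutrophils) to 0.801 (macrophages), so their signs are not independent counts. Of the immune checkpoint genes 3 of 14 rose, among them the ligand genes Pdcd1lg2 (log2 change 2.17, SE 0.417) and Cd274 (1.43, SE 0.397). Of MHC class I genes 6 of 20 and of MHC class II genes 1 of 10 rose, with an adjusted p of 0.39 each with an estimated correlation.

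The cGAS-STING list passed upward in KPC (median 0.442), with 1 of 20 members higher and 1 lower by edgeR and an adjusted p of 0.43 with an estimated correlation. Its member Sting1, the adaptor STING, rose from 123.3 ± 16.1 to 165.3 ± 16.8 CPM. Of interferon-stimulated genes 2 of 45 passed as higher, Ifi35 and Isg20, while 44 had a positive and 1 a negative change. Their median was 0.432, with an adjusted p of 0.504 with an estimated correlation (0.762). Of interferon-gamma response genes 3 of 25 passed as higher and 25 had a positive change (median 1.35). Their adjusted p was 0.397 with an estimated correlation (0.922). Signs within these lists are not independent counts either. Of inflammatory genes 7 of 20 and of T cell recruiting chemokines 2 of 12 rose, each with an adjusted p of 0.39 with an estimated correlation. Of epithelial genes 9 of 15 rose and 1 fell, with an adjusted p of 0.177 with an estimated correlation, and of hypoxia genes 1 of 20 rose (0.55). Proliferation genes (5 of 26 lower, among them Cenpf and Mcm6) and double-strand break repair genes (4 of 27 lower, among them Rif1 and Brca2) passed downward, with adjusted p of 0.504 and 0.482 with an estimated correlation. Skeletal muscle genes (median -2.05) and adipocyte genes (median -1.19) also passed downward with 0 single genes called, each with an adjusted p of 0.504 with an estimated correlation. The muscle transcript Acta1 ranged from 177 to 7320 CPM in wild-type and from 2.14 to 1600 CPM in knockout libraries. Fibroblast genes (median 0.165) and endothelial genes (median 0.123) did not pass.

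**Figure D3:**
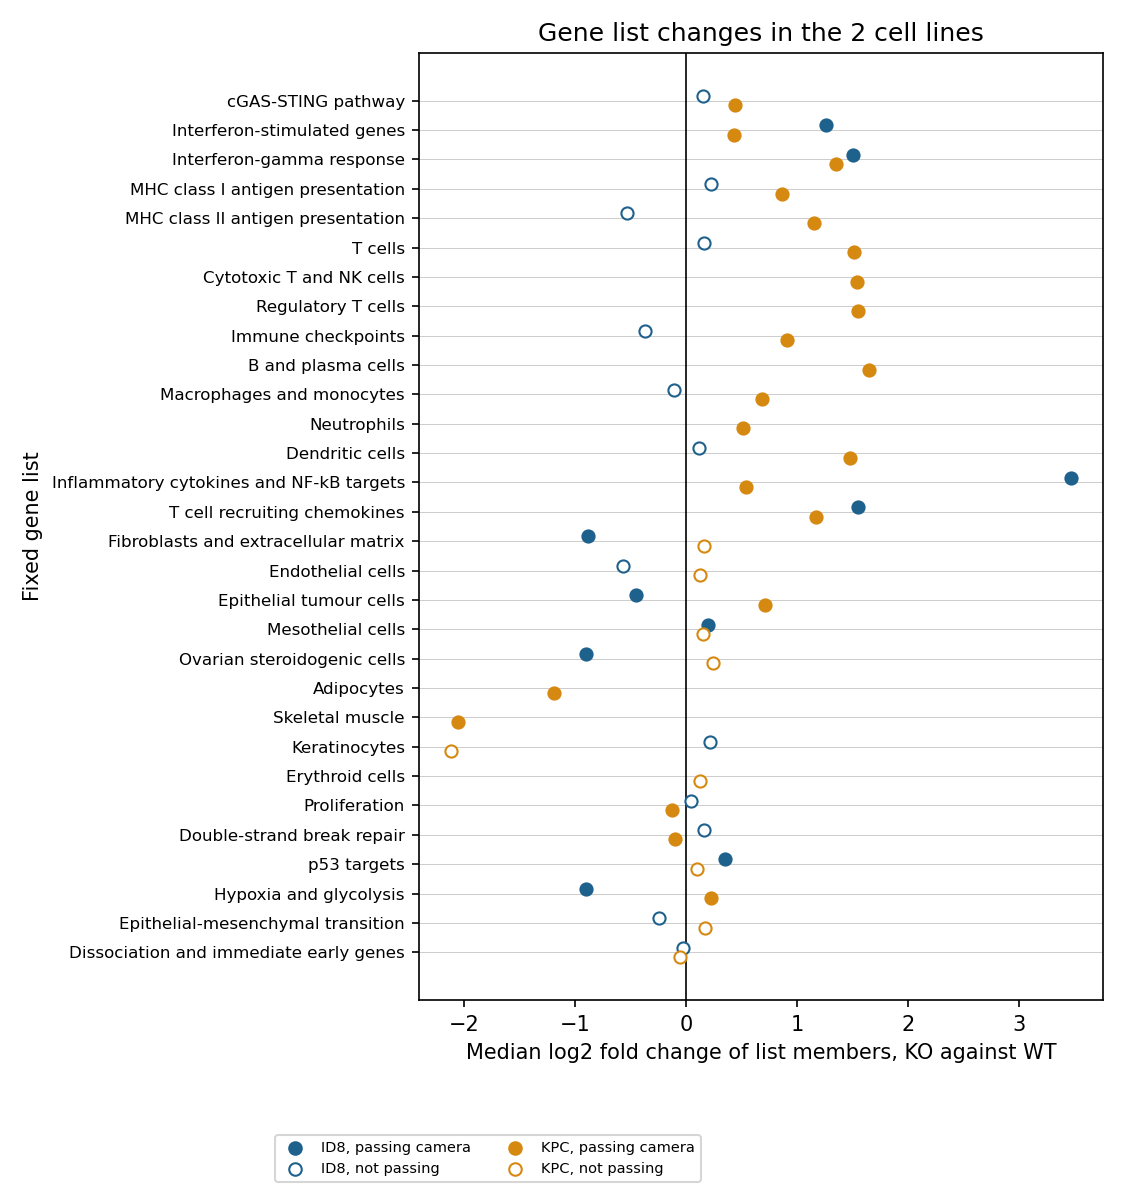
Median log2 fold change of the members of each fixed gene list, knockout against wild type, in ID8 (blue) and KPC (orange), with filled points for lists that pass camera with a preset correlation. The inflammatory list lies at 3.47 in ID8 and 0.54 in KPC, and hypoxia genes lie at -0.902 in ID8 and 0.225 in KPC.

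The largest fitted decreases in KPC knockout were those of St8sia3, Crisp1, Muc6, Csrp3, Mab21l4 and Pitpnm3. With the skeletal muscle score as a covariate Csrp3 lost its call (log2 change -4.46, SE 0.936, and -4.26, SE 1.15, with the covariate). St8sia3 had 464 counts over all wild-type and 1 over all knockout libraries, a ratio of 460 with a 95% counting interval of 82.1 to 18200. Crisp1 fell from 55.3 ± 17.8 to 0.445 ± 0.253 CPM. Besides Chil4 and Chil3, the largest fitted increases were those of Rnase2a, Gsdmc2, Lypd8 and Clca1. Lypd8 also lost its call with the muscle covariate (log2 change 5.39, SE 1.02, and 4.42, SE 1.19, with the covariate).

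The knockout effect differed between the lines for 3259 of 14921 genes, 1729 with a more positive and 1530 with a more negative change in KPC (edgeR interaction). The 14921 genes were not limited to the 11600 tested in both lines. Ace, the angiotensin-converting enzyme gene, fell from 231.2 to 23.25 CPM in ID8 and from 206.1 to 169.5 CPM in KPC, a log2 difference of 3.06 (SE 0.115). Adgrg1 fell by 2.58 on the log2 scale in ID8 and rose by 0.55 in KPC. Kif21b, Kctd14 and Ly6e had log2 differences of 3.31, 3.76 and 2.15. Among lists, interferon-stimulated genes (median difference -0.779) and inflammatory genes (-0.668) had a more negative change in KPC, and hypoxia (1.18), epithelial (1.15), fibroblast (0.948), ovarian steroidogenic (1.15) and MHC class I genes (0.644) had a more positive change there. Proliferation (-0.176) and double-strand break repair genes (-0.178) had a more negative change. These were 9 of 31 lists with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.212. Several list medians include members that did not pass the count filter in ID8. The interaction tested 20 inflammatory, 20 MHC class I and 20 fibroblast genes, against 13, 14 and 13 in ID8 alone. For members with 0 counts in ID8, the difference reflects the KPC change alone. The fit shares its spread between lines whose variation was 5.08% and 25.1%, and the lines also differed in the level of most host list members.

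Without a fold cut, genes called in both lines changed in opposite directions more often than independent lists would give. Of 11600 genes tested in both, 344 changed in the same direction, where 365 were expected, and 493 in opposite directions, where 365.9 were expected. Genes higher in ID8 and lower in KPC numbered 277 (212.3 expected, Fisher's exact adjusted p = 3.66e-07), and those lower in ID8 and higher in KPC numbered 216 (153.6 expected, adjusted p = 3.02e-08). Genes higher in both numbered 134 (156.1 expected, adjusted p = 0.0479) and genes lower in both 210 (208.9 expected, adjusted p = 0.934). Among genes changed at least 2-fold in both, 27 changed in the same direction, where 4.61 were expected, and 23 in opposite directions, where 4.97 were expected (Fisher's exact adjusted p of 0.00336 or less in each of the 4 combinations). Genes are not independent replicates, which neither Fisher's exact test nor a correlation across genes allows for. Across genes, fold changes had a Pearson r of 0.00887 and a Spearman rho of -0.0777. The lines also differed in the level of most host list members, which the overlap does not allow for. Among genes that changed alike, Ifitm1, Slc26a9 and Kcnh2 fell and Pglyrp2, Nos2 and Gbp8 rose in both lines. Nos2, the inducible nitric oxide synthase gene, had log2 changes of 2.85 in ID8 and 1.70 in KPC.

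**Figure D4:**
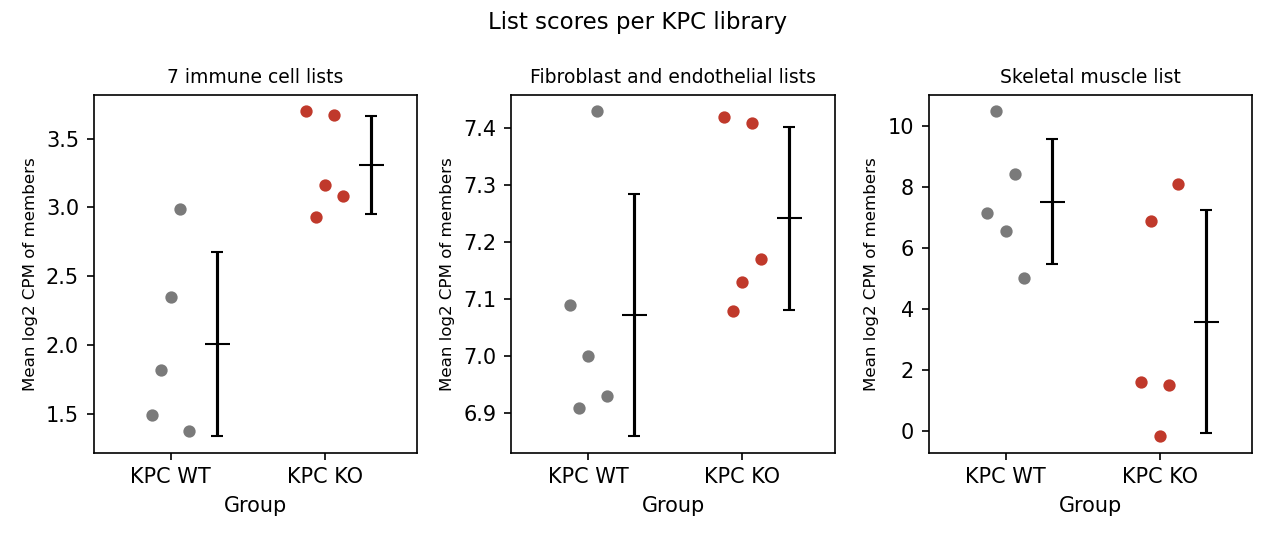
Mean log2 CPM of the members of 7 immune cell lists, of the fibroblast and endothelial lists, and of the skeletal muscle list in each KPC library (points), with group mean and SD. The immune score is 2.01 ± 0.669 in wild type and 3.31 ± 0.354 in knockout, and the muscle score 7.54 ± 2.08 and 3.58 ± 3.67 (SD, n = 5 each).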

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

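Tests on depth, filtering, host tissue, tumour share, muscle and random gene sets were chosen after the result was seen. Those on GC content, parts of chromosomes and other splits of the samples were set before their own results. The chromosome pattern itself was found in the data before its tests were set.

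In ID8 libraries, labelled as tumours, 18 of 21 T cell, 19 of 20 macrophage, 12 of 14 endothelial and 7 of 8 erythroid list members were under 0.1 of their KPC level, with exceptions such as Esam (140 against 47.6 CPM) and Flt1 (30.1 against 49.8). Lower depth is argued against, since mean ID8 totals were 102% of KPC totals. Removal of rare genes is argued against by 4620 genes that the ID8 tables list with totals under 10 counts. Leukocyte, endothelial and red blood cell RNA at KPC levels is argued against. Ptprc, Adgre1, Cdh5 and Hbb-bs had 0 counts in every ID8 library. Pecam1 of the endothelial list reached at most 2.59 CPM in ID8 and was 81.7 to 152 CPM in KPC. RNA of cancer cells with little host tissue thus remains a candidate explanation. The median ID8 to KPC ratio over 4 host cell lists (2.77e-05) restates the observation and decides nothing. The labels' protocols describe extraction from cells, and how these were obtained is not given in the sources used here.

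Immune cell lists were higher in KPC knockout libraries with a preset correlation. Each of the 7 lost this call with an estimated correlation (adjusted p = 0.39). By fry, which does not set a list against other genes, each passed (adjusted p of 0.0234 to 0.0461). The mean score of 7 immune lists rose by 1.3 (exact permutation p = 0.0159), but the number of lists passing is no evidence of its own, since 23 of 100 splits of the samples gave at least the 21 lists of the real split and the highest other gave 25. A lower share of tumour cells alone is argued against, since the immune score rose relative to the fibroblast and endothelial score (exact permutation p = 0.00794). Muscle in wild-type libraries as the whole cause is argued against, since the immune score kept a difference of 1.22 with the muscle score in the model (permutation p = 0.0305 over all orders of the residuals), a test that replaced one on list medians (1.25 with that covariate, against 1.51) after the scores of each library were known. A difference in immune cell content between genotypes stays open and may fit, but was found and tested on the same libraries; with the muscle covariate 34 named gene values lost their call as SEs grew to a median of 1.27 times, while a median of 93% of their log2 change was left.

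In ID8 knockout libraries, genes of chromosome 15 (median log2 change -0.297, 414 genes) and X (-0.348, 327 genes) were lower and those of chromosome 19 higher (0.223, 385 genes), by the GRCm38.p6 assembly. Random gene sets matched on expression argue against chance among genes (permutation p = 1e-04, the smallest that 10000 sets can give). GC content and length are argued against, since at least 96.8% of each median was left after removing their trend. A change of copy number of whole chromosomes in the knockout line is a candidate explanation, as both parts of each chromosome, divided at its middle gene, kept at least 93.1% of the whole median. DNA was not analysed here, and a clonal difference cannot be separated from the knockout, because each genotype is represented by a single line in the labels.

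In ID8, 1 of 10 splits gave as many genes as the real one (6067, highest other 0), and 2 of 10 gave as many lists (10, highest other 11), but 10 splits are too few for a share under 0.05. In KPC, 1 of 100 splits, the real one, gave as many genes (1953, highest other 1458), so a chance split of the samples is argued against. For the difference between lines, 1 of 100 splits, the real one, gave as many genes (3259, highest other 1767). These splits shuffled genotype in both lines, so they compare with no effect in either line. They cannot decide whether the effect differs between lines. Of the same splits, 22 of 100 gave as many lists (9, highest other 14), so the number of lists is no evidence of its own.

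In KPC groups of 5, a single library stood far from the others for 19 of 194 values. Chance flags about 1 in 20 for independent values of normal spread. The CPM used were not logged and some genes move together, so that rate need not hold here. Knockout replicate 2 was low for Sting1 (137 CPM), Isg20 (33.5), Psmb10 (95.3), the MHC class I score (6.55) and the T cell recruiting chemokine score (3.48). Wild-type replicate 4 was high for Chil4 (8.83 CPM), Socs1 (19.4) and Cd2 (11). Wild-type replicate 2 was high for Myh2 (119 CPM) and Mb (107), and knockout replicate 5 for Myh2 (5.81) and Mb (13.2). Knockout replicate 4 was high for Jchain (103 CPM) and Mzb1 (3.94), and knockout replicate 1 for Mab21l4 (3.75) and Ifitm1 (21.8). Wild-type replicate 5 was high for Muc6 (17.6 CPM) and low in total count (17902867), and knockout replicate 3 held the only counts of St8sia3 in its group (0.0516 CPM).

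The knockout effect differed between lines for 40 named genes, by the log2 change in KPC minus that in ID8. It was more negative in KPC for Saa3 (-5.8), Oas2 (-6.74), Oas1g (-4.45), Steap4 (-4.72), Ccl20 (-3.21), Neurl3 (-3.95), Oas1a (-3.8), Vcam1 (-3.29), Ccl2 (-3.23), Rspo1 (-1.82), Aen (-0.97), Zmat3 (-1.01), Cenpf (-0.789), Rif1 (-0.7) and Kcnh2 (-1.62). It was more positive for Trp53bp1 (0.757), Pmaip1 (10.7, a fitted value that is no bound), Tspan11 (5.84), A4galt (6), Slc44a3 (5.87), Myl9 (4.99), Cd276 (0.576), Col6a2 (1.07), Acta2 (1.99), Elf3 (2.24), Krt18 (1.04), Star (1.07), Pdk1 (1.21) and Ldha (0.881). The same held for Sting1 (0.511), Aim2 (1.67), Psmb10 (1.2), Cldn3 (1.12), Egln3 (2.11), Slc2a1 (1.23), Ace (3.06), Adgrg1 (3.16), Kif21b (3.31), Kctd14 (3.76) and Ly6e (2.15). Of the lists, median differences were -0.779 for interferon-stimulated, -0.668 for inflammatory, -0.176 for proliferation and -0.178 for break repair genes. They were 0.644 for MHC class I, 0.948 for fibroblast, 1.15 for epithelial, 1.15 for ovarian steroidogenic and 1.18 for hypoxia genes, none of which passed with an estimated correlation. Except for the hypoxia, proliferation and break repair lists, these medians include members that did not pass the count filter in ID8.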

How the results depend on the processing

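The muscle score covariate, the removal of libraries with Acta1 above 1000 CPM and the removal of chromosomes 15, 19 and X were chosen after the data were seen. No named gene and no called list changed sign under the alternatives run, and the skeletal muscle list was not tested against its own score. Of the named gene values under alternatives, 1886 kept their side of the threshold, 154 lost it and 23 gained it, and of the list values 589 kept it and 66 lost it, 36 of these with an estimated correlation. ID8 gene counts went from 6067 to 747 with the fold cut and 2681 in the joint fit of 4 groups. They were 5355 to 5786 with single libraries left out and 5020 without the 3 chromosomes. KPC gene counts went from 1953 to 550 with the fold cut, 3195 with DESeq2, 3156 with limma-voom, 3524 in the joint fit and 335 with the muscle score, where 34 named gene values lost their call with larger SEs. Single libraries left out gave 934 (without wild-type replicate 1) to 3106 (without wild-type replicate 4), and 9 of the 10 such fits moved the count by over 1.5 times: 952, 1195, 1284, 1232, 1133, 1059 and 1178 without wild-type replicates 5, 2 and 3 and knockout replicates 1, 3, 4 and 5. Without the 4 libraries with muscle transcripts the count was 2020. The interaction count of 3259 became 975 with the fold cut and 4902 with limma-voom. List counts went from 10 to 4 (estimated correlation) and 18 (fry) in ID8, from 21 to 0 (estimated correlation) in KPC, and from 9 to 0 (estimated correlation) for the difference. Over all comparisons, 15 list values and 104 named gene values lost their call with a single library left out, and not all of them are named here. In KPC the double-strand break repair call was lost without wild-type replicates 1, 3 or 5 or knockout replicates 1, 4 or 5. The hypoxia call in KPC was lost without wild-type replicate 1 or knockout replicates 1, 4 or 5. Trp53bp1 in ID8 was -1.25 on the log2 scale without TMM, against -1.33 with it. The overlap of calls between the cell lines held 637 alike and 952 opposite at an adjusted p of 0.1, and 27 and 23 with the fold cut. The cause of these changes was not tested. Same-numbered samples correlated at -0.13, 0.29 and -0.17 in ID8 and at -0.16, 0.64, 0.24, 0.26 and -0.61 in KPC. These values do not show that the numbers pair samples, and with so few samples they cannot exclude it. With a replicate block 5852 genes passed in ID8, 1665 in KPC and 2755 in the interaction, lists numbered 10, 20 and 9, calls in both lines 283 alike and 354 opposite, and Trp53bp1 had log2 changes of -1.33 and -0.60 and a difference of 0.75. Not every sample correlated best with its own number. Depth was alike in all groups, and 3 counts correspond to at most 0.1676 CPM of the unscaled totals.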

Other observations

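Genes of eosinophils and type 2 responses were higher in KPC knockout libraries. This group was written after some of its members had been seen among the largest increases, and its tests were chosen after the result was seen. Of 13 tested members 12 rose, with a median log2 change of 3.38. Ccl24, an eosinophil-attracting chemokine gene, rose from 6.64 ± 3.33 to 74.3 ± 48.3 CPM, its receptor gene Ccr3 from 1.26 ± 1.11 to 15.3 ± 9.77 CPM and Alox15 from 4.26 ± 1.56 to 44.4 ± 24 CPM (SD, n = 5 each). The 4 members not seen when the group was noticed were Ccl11, Ear2, Siglecf and Il5ra, of which the former 3 rose. Siglecf, a surface marker of eosinophils, rose from 2.87 ± 0.584 to 15.4 ± 9.62 CPM, while Il5ra was at 160 ± 23.4 and 173 ± 29.7 CPM. These 4 had a median log2 change of 1.82, below the 3.38 of all 13, and gave p = 0.0346 in camera with an estimated correlation. A larger eosinophil or type 2 component in the knockout samples may thus be a hypothesis to follow up. The test rests on 4 genes, was set after their values had been printed, and was not adjusted for other groups that were noticed.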
